A study of Homo sapiens with 5 samples.

How the data were processed

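PBRM1 (Baf180, a subunit that marks the PBAF form of the SWI/SNF chromatin remodelling complex) was mapped by chromatin immunoprecipitation and sequencing in HAP1, a near-haploid human line derived from a chronic myeloid leukaemia. Per the labels' protocols, cells were left untreated or were given interferon gamma (IFN-γ) at 50 µg/mL, the unit the labels use, for 5 days, with medium and cytokine renewed between days 2 and 3. Per the same protocols, cells were fixed in 1% formaldehyde for 12 min, chromatin was sonicated, and each library was read to at least 40 M pairs of 150 bp. Precipitation used 2 antibodies against PBRM1, one sold by Bethyl and one by Novus. The series has 5 samples. Of these, 1 is input chromatin without precipitation, for which no peak list was analysed here. The other 4 are single libraries of each antibody in each treatment, so every group has 1 library and no comparison has a replicate check.

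Per the submitters' processing notes, the tools were FastQC 0.11.5, Bowtie2 2.3.4.3, SAMtools 1.3.1, deepTools 3.5.0 and MACS2 2.2.7.1, and the genome build was hg19. Filters on reads, the peak caller's settings and which library served as control are not given in the sources used here. One peak list was deposited per library, so peaks were called per sample and not on pooled samples. Each deposited peak has an interval, a summit and an integer score, which was not used. The fold enrichment, a ratio of the summit's pileup to its local expectation, is the authors' own value for each peak. It served to describe, rank or filter peaks within a list and, with the p-value, to estimate depth and thin the lists as described below. The −log10 p-value that the authors deposited for each peak served mainly for that estimate. Their −log10 q-value served only to describe, rank or filter peaks within a list. In every list the smallest −log10 q lay just above 4, and no interval was repeated. Coordinates are given 1-based in hg19.

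Lists were compared by intervals that shared at least 1 bp, counted with bedtools 2.31.1 and again in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with equal counts. Shares have exact (Clopper-Pearson) 95% binomial intervals from SciPy 1.17.1, which cover counting error only. Each overlap was set beside the mean of 100 random placements of the first list within its chromosomes. The 4 lists were then merged into regions, and the libraries with a peak in each region gave its combination. The number of regions expected under independence was n1 × n2 / N over the merged regions. It takes differences between treatments as independent between antibodies, and for combinations that follow the antibody, differences between antibodies as independent between treatments. Regions named in the text are the 10 of each combination with the highest minimum percentile of fold enrichment, each percentile taken within its own list. These comparisons, this rule, 15 gene lists and the alternatives listed as planned were fixed before the data were examined. No test across libraries was made and no p-value is given.

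A gene annotation and sequence of the full hg19 genome were not used here, so motif content, exon and intron location, promoter CpG matching and the promoter values of single genes set down in advance were not run. Partial hg19 resources were used in their place, chosen after the peak lists had been opened. Cytogenetic bands came with circlize 0.4.16 and chromosome lengths with GenomeInfoDb 1.38.1. Gene models of 329 protein-coding genes came with GenomicFeatures 1.54.1 and pyranges 0.1.4, and CpG islands of chromosome X with pyranges. The build of the pyranges tables is not stated there. Of 291 genes from that source, 6 lay at their GRCh38 position, and gene ends stayed within hg19 chromosome lengths. This does not check each model. On chromosome 6, STK19 ran from 3449402 to 31981961 and TRIM40 from 1344152 to 30116505, far longer than a gene. Some of their transcription starts may thus be misplaced, and both genes were kept. Symbols were matched through a RefSeq table of the GRCh38 assembly, used for names only. A promoter was the 1000 bp on each side of a transcription start. The lists held 415 symbols beside the olfactory receptors, and 10 listed genes, 2 of them olfactory receptors, had coordinates. The test of each list against random lists was therefore void. A set of 19 bands that carry textbook interferon genes was written down before any count by band was seen.

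Depth was read from the deposited values. A fold enrichment and a −log10 p-value together fix the summit's pileup and its local Poisson expectation, with a pseudocount of 1 in the ratio. The pileup came out whole, within 0.001, for 99.7% and 99.1% of peaks in the untreated Bethyl and Novus lists and for 99.6% and 99.5% in the IFN-γ lists. On simulated peaks, 2986 to 2990 per library, 100% of pileups were recovered. These peaks were made with the formula that the recovery inverts, so this checks the arithmetic only. It does not test the readings of background coverage and fragment length that follow. The smallest expectation in a list was taken as its background coverage. The narrowest interval was taken as the mean fragment length, the peak caller's default minimum width, and coverage over length as the relative fragment number. It was 183 bp in untreated Bethyl, 185 in untreated Novus, 234 in IFN-γ Bethyl and 123 in IFN-γ Novus. The last is shorter than the 150 bp reads, so the fragment number of IFN-γ Novus is uncertain. So is each result at equal fragment number. To compare lists at like depth, summit pileups were thinned by binomial draws to the lowest coverage or the lowest fragment number, and peaks with a recomputed −log10 p of at least 8 were kept. Thinning could only remove deposited peaks. It was chosen after the data were seen. Alternatives planned for the lists were a −log10 q of at least 5, a fold enrichment of at least 4, equal list lengths by q, chromosomes 1 to 22 and X only, a reciprocal overlap of 50%, and summits within 200 bp. Plots were drawn with matplotlib 3.10.9.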

Results

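PBRM1 occupancy was measured in HAP1 cells with and without 5 days of IFN-γ, using 2 antibodies against the protein, and the 4 resulting peak lists held 71219 peaks. The question put by the design is where on chromatin the PBAF complex sits in the basal state and after the cytokine. The antibodies serve as a check on each other within a treatment. Each combination of antibody and treatment has 1 library, so no difference between treatments has a replicate check. Intervals on shares cover counting error within a library only.

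The lists differed in length, and with IFN-γ they moved in opposite directions for the antibodies. The Bethyl antibody gave 21963 peaks in untreated cells and 10480 after IFN-γ, a ratio of 0.477. The Novus antibody gave 10227 peaks in untreated cells and 28549 after IFN-γ, a ratio of 2.79. PBRM1 peaks covered 13.9 Mb and 5.08 Mb in the untreated Bethyl and Novus lists, and 7.19 Mb and 17.9 Mb in the IFN-γ lists. Median peak widths were 464, 391, 550 and 414 bp in the order untreated Bethyl, untreated Novus, IFN-γ Bethyl and IFN-γ Novus, and median fold enrichments were 4.73, 4.64, 5.28 and 4.37. Libraries were not equally deep. Background coverage recovered from the peak values was 4.05, 4.08, 3.01 and 5.87 fragments in the same order, and the estimated number of fragments relative to the untreated Novus library was 1.00 for untreated Bethyl, 0.583 for IFN-γ Bethyl and 2.16 for IFN-γ Novus. After thinning to equal background coverage, the Bethyl lists held 14882 peaks without and 10077 with IFN-γ, a ratio of 0.677, and the Novus lists 7008 and 13384, a ratio of 1.91. After thinning to equal fragment number, the Bethyl lists held 11337 peaks without and 10077 with IFN-γ, a ratio of 0.889, and the Novus lists 4990 and 5414, a ratio of 1.08. Fold enrichments are the authors' values and describe peaks within a list, not differences between lists.

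**Figure D1:**
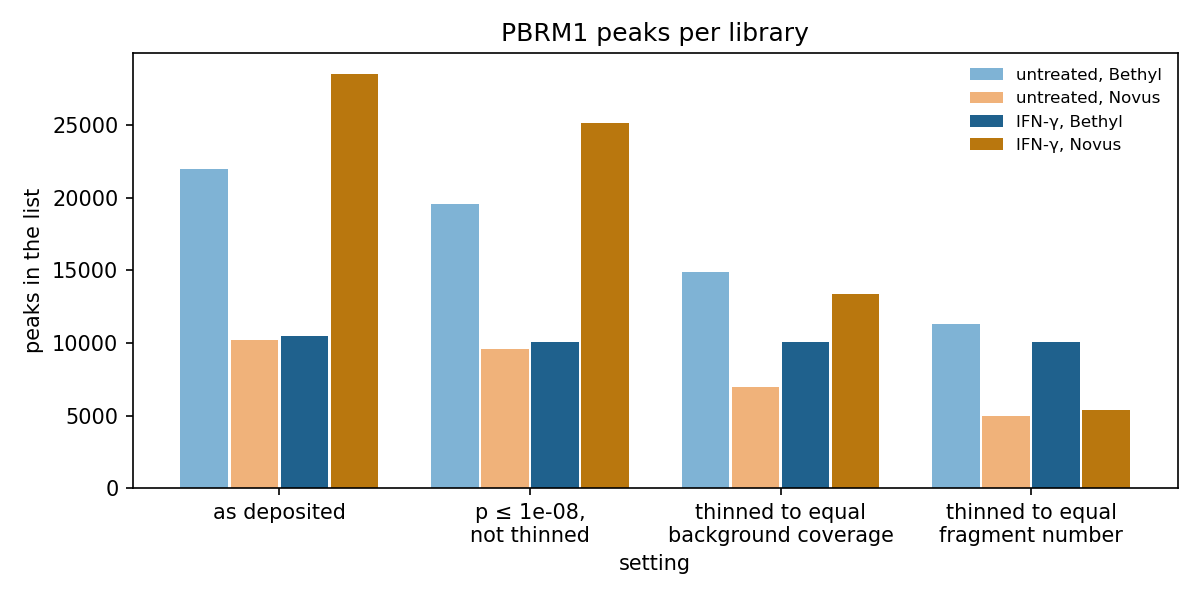
Bars give the number of PBRM1 peaks (y axis) in each of the 4 libraries, one library per bar, for the lists as deposited, at a recomputed p threshold and after thinning to equal background coverage or equal fragment number (x axis). As deposited, the Bethyl pair goes from 21963 to 10480 and the Novus pair from 10227 to 28549 with IFN-γ, while at equal fragment number the pairs are 11337 to 10077 and 4990 to 5414.

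Within a treatment, most peaks of the shorter list met a peak of the longer one when an overlap of 1 bp was enough. Of the untreated Novus peaks, 93.0% (95% interval 92.5 to 93.5) overlapped an untreated Bethyl peak, and of the IFN-γ Bethyl peaks, 98.1% (97.8 to 98.4) overlapped an IFN-γ Novus peak. In the reverse direction the longer lists were matched in part, at 39.7% for untreated Bethyl in Novus and 35.1% for IFN-γ Novus in Bethyl. Random placement gave means of 0.977% and 1.37% for the first pair of shares and 0.443% and 0.523% for the second. For untreated Novus in Bethyl and then IFN-γ Bethyl in Novus, the shares were 61.2% and 66.1% when summits had to lie within 200 bp, 43.3% and 59.0% with a reciprocal overlap of 50%, and 83.2% and 42.7% at equal fragment number, where IFN-γ Novus had the shorter list of its pair.

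Merging the lists gave 33362 regions, of which 6581 (19.7%) had a peak in all 4 libraries. The strongest of these by the least favourable rank was in 15q15.3, on chromosome 15 from 44580055 to 44581644, with fold enrichments of 61.2 and 60.8 in untreated Bethyl and Novus and of 87.5 and 110 in the IFN-γ libraries. The next were 3 regions within 1q21.2. They spanned 149810679 to 149815657, 149821328 to 149826402 and 149856506 to 149860510 on chromosome 1, with fold enrichments in untreated Bethyl of 50.0, 44.9 and 37.4. On chromosome 6 there was a region from 27099166 to 27102361 in 6p22.1 and another from 26156366 to 26160042 in 6p22.2. The remaining leading regions were in 1q25.3 (180991150 to 180992496), 17q11.2 (31149429 to 31149893), 21p11.2 (9825365 to 9827592) and 1q22 (156186223 to 156186666). Region 21p11.2 lies on an acrocentric short arm, where repeated sequence makes read placement less certain. No filter for sites of artefactually high signal was applied to the merged regions. A high rank alone therefore does not show that a region is bound by PBRM1.

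Promoter occupancy followed list length among the 329 protein-coding genes with a gene model here. Peaks overlapped the promoters of 204 genes (62.0%, 56.5 to 67.3) in untreated Bethyl, 129 (39.2%, 33.9 to 44.7) in untreated Novus, 141 (42.9%, 37.4 to 48.4) in IFN-γ Bethyl and 222 (67.5%, 62.1 to 72.5) in IFN-γ Novus. Windows moved by 1000000 bp were hit for 2.43%, 1.52%, 1.82% and 3.34% of these genes. With lists of equal length, 38.6%, 39.2%, 41.9% and 40.7% of the promoters had a peak. A promoter peak was present in all 4 libraries for 103 genes. Of those with all 4, the best ranked was KLHDC9 on 1q23.3 (161068151 to 161070136), with fold enrichments of 13.4, 10.6, 13.5 and 26.8 in untreated Bethyl, untreated Novus, IFN-γ Bethyl and IFN-γ Novus. It was followed by the histone H4 gene HIST1H4B, by CTBP2, a transcriptional corepressor, by NID1, which encodes the basement membrane protein nidogen, and by ATP1B1, the beta subunit of the sodium pump. The next 5 were SCRN1, the ubiquitin ligase gene UBE3A, the ubiquitin-conjugating enzyme gene UBE2J2, SH3KBP1 and ETV6, a transcriptional repressor of the ETS family. The lowest fold enrichment among these 10 genes in any library was 6.08, for SH3KBP1 in untreated Novus.

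Of the gene lists set down in advance, few members had coordinates, and these are given as single genes. The histone genes HIST1H4B, HIST1H4C and HIST1H4H, on 6p22.2, had a promoter peak in every library, with fold enrichments in untreated Bethyl of 8.52, 10.5 and 8.60, in IFN-γ Bethyl of 8.33, 3.91 and 7.49, in untreated Novus of 6.50, 5.32 and 5.12 and in IFN-γ Novus of 12.5, 6.98 and 10.2. NFKB2, which encodes the p100 precursor of an NF-κB subunit, had a promoter peak in 3 libraries, at 4.31 in untreated Bethyl, 3.90 in untreated Novus and 5.24 in IFN-γ Novus. The interferon-inducible genes CASP1 and SAMD9L had none in any library, and neither did the neuronal gene MAP2 or the 2 olfactory receptor genes in the sample. TAPBPL, a peptide editor of the MHC class I pathway, had a peak in both IFN-γ libraries only. The lists of JAK-STAT signalling, MHC class II, checkpoint ligand, PBAF and BAF subunit, ribosomal protein, immediate-early, cell cycle, haematopoietic and hepatocyte genes had 0 members with coordinates.

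On chromosome X, where CpG islands could be placed, PBRM1 peaks lay mostly in islands. The shares were 70.2% of 600 peaks in untreated Bethyl (66.3 to 73.8), 83.0% of 241 in untreated Novus (77.6 to 87.5), 89.2% of 288 in IFN-γ Bethyl (85.1 to 92.6) and 60.1% of 833 in IFN-γ Novus (56.7 to 63.5). Peaks moved by 1000000 bp fell in islands in 0.720% to 1.66% of cases. Regions with a peak in all 4 libraries were in islands in 95.4% of 153 cases, and regions found in the IFN-γ Novus or the untreated Bethyl list alone in 30.3% of 330 and 26.8% of 112. Across chromosomes 1 to 22 and X, Giemsa-negative bands, the gene-rich part of the karyotype, held 65.2%, 66.0%, 65.0% and 62.1% of peaks in the 4 lists in the order given above, against 42.4% of the sequence. The darkest bands held 4.06%, 4.07%, 4.95% and 4.68% against 16.4%.

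Between treatments, most PBRM1 peaks of the shorter list met a peak of the longer one at an overlap of 1 bp. Of the IFN-γ Bethyl peaks, 90.9% (90.3 to 91.4) overlapped an untreated Bethyl peak, and of the untreated Novus peaks, 94.3% (93.9 to 94.8) overlapped an IFN-γ Novus peak. In the other direction the shares were 43.4% of untreated Bethyl and 31.0% of IFN-γ Novus peaks. Random placement gave means of 1.11%, 1.22%, 0.527% and 0.437%. The corresponding shares of the shorter lists, Bethyl and then Novus, were 58.9% and 38.6% with a reciprocal overlap of 50% and 72.0% and 50.2% at equal fragment number. In the lowest 10% of the untreated Bethyl list by fold enrichment, 91.2% of peaks were absent from the IFN-γ Bethyl list, against 4.50% in the top 10%. For untreated Novus peaks absent from IFN-γ Novus the shares were 6.48% and 5.87%, and 0.311% in the top 10% on chromosomes 1 to 22 and X alone. With lists of equal length, the mean overlap of the pairs of one treatment was 74.0% untreated and 76.0% with IFN-γ, that of the pairs of one antibody 72.1% for Bethyl and 70.4% for Novus, and that of the pairs differing in both 71.7% and 67.8%.

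A change seen with both antibodies was found at a small part of the regions. A peak in both IFN-γ libraries and neither untreated library was present at 544 regions (1.63%, 1.497 to 1.77), where 395 would be found if the antibodies were independent. The opposite combination, both untreated and neither IFN-γ library, was present at 183 (0.549%, 0.472 to 0.634) against 160. Combinations that followed the antibody lay below the number given by independence between treatments, at 43 for both Bethyl libraries alone against 60.9 and 240 for both Novus libraries alone against 296. The combination of the longer lists, untreated Bethyl with IFN-γ Novus, was present at 3999 regions, against 6387 under independence between antibodies, and its counterpart at 0 against 9.88. All these expectations are taken over merged regions, which have a peak in some library by construction. They change with that choice, so an excess or a shortfall against them does not measure agreement between libraries. The IFN-γ combination outnumbered the untreated one by 2.97 times, and by 1.34 times with lists of equal length, 1.32 at equal fragment number, 1.54 with a reciprocal overlap of 50% and 1.43 with summits within 200 bp.

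**Figure D2:**
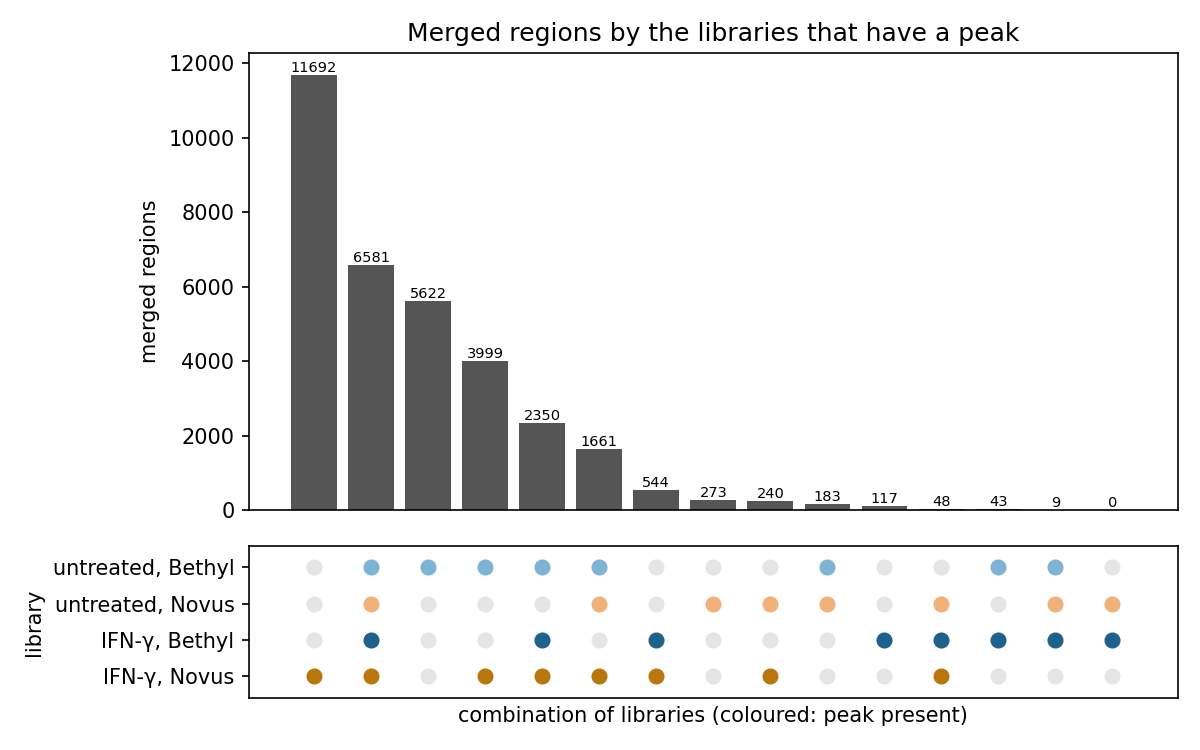
Bars give the number of merged regions (y axis) for each combination of the 4 libraries, with coloured dots under a bar marking the libraries that have a peak. Regions seen in IFN-γ Novus alone (11692), in all 4 libraries (6581) and in untreated Bethyl alone (5622) are the most frequent, and 544 regions are seen in both IFN-γ libraries alone.

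The leading IFN-γ region was in 14q32.2, on chromosome 14 from 100794490 to 100819358, 24869 bp long, with fold enrichments of 20.6 in IFN-γ Bethyl and 22.99 in IFN-γ Novus and no peak in either untreated library. It ranked in the top 10% of both IFN-γ lists, as did the other 9 regions named here. They lay in Xq24 (117187619 to 117188033), 1q31.1 (190447237 to 190448339), 8q24.3 (145479506 to 145482950), 7p14.3 (30560232 to 30560712), 4q28.2 (129473938 to 129474675), 17q25.3 (80013786 to 80019848), 13q34 (110383029 to 110383325), 10q26.3 (132158484 to 132158957) and 17p13.1 (8129487 to 8130663). Their fold enrichments in IFN-γ Bethyl ran from 7.84 to 12.2. In the IFN-γ Bethyl list, 385 of the 544 regions (70.8%, 66.8 to 74.6) ranked at or under the 50th percentile and 18 in the top 10%. In the IFN-γ Novus list, 175 (32.17%, 28.3 to 36.3) ranked at or under the 50th percentile and 51 in the top 10%.

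Of the regions with a peak in both untreated libraries alone, the leading one was in 1p36.32, on chromosome 1 from 3447198 to 3448674, with fold enrichments of 7.33 in Bethyl and 6.69 in Novus. In the Bethyl list 5 of the 183 ranked in the top 10%, and in the Novus list 2. The next were in 22q13.31 (45371135 to 45371857), at 10.7 and 6.30, and in 19p13.3 (1811592 to 1812282), at 7.33 and 6.10. The other 7 lay in 19q13.33, 10p13, 7q22.1, 4q21.21, 3p25.2, 9q34.3 and 3q22.1. The 10 leading regions of the combination of untreated Bethyl with IFN-γ Novus, among them regions in 8q24.3 (144691061 to 144692240), 6p22.3 (15244797 to 15245675) and 7p22.1 (6570232 to 6571132), had fold enrichments from 6.24 to 7.44 in untreated Bethyl.

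Among the sampled genes, 6 had a promoter peak in both IFN-γ libraries and neither untreated library, and 1 had the opposite. In order of rank the 6 were TAPBPL, ZCCHC10, TLR2, a pattern recognition receptor for bacterial lipoproteins, the nucleolar protein gene NOLC1, MAPRE2, which encodes a microtubule end-binding protein, and PPME1, a methylesterase of protein phosphatase 2A. At TAPBPL, on 12p13.31 (6561208 to 6571482), the peaks ran from 6561301 to 6561595 in IFN-γ Bethyl, at a fold enrichment of 5.45, and from 6561335 to 6561815 in IFN-γ Novus, at 4.95. At TLR2, on 4q31.3 (154605441 to 154627242), the values were 4.31 and 4.95. The gene with the opposite combination was ANK2, which encodes ankyrin B, at 3.79 in untreated Bethyl and 4.53 in untreated Novus. None of the 7 ranked in the top 10% of both lists that held its peak.

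Bands that carry interferon genes held 34 of the 544 IFN-γ regions (6.25%, 4.37 to 8.62), 238 of the 6581 regions of all 4 libraries (3.62%, 3.18 to 4.10) and 3 of the 183 untreated regions (1.64%, 0.339 to 4.72). The band 1p22.2, home of the guanylate-binding proteins GBP1 to GBP5, had 6 IFN-γ regions beside 9 seen in all 4 libraries and 0 of the untreated combination. The band 21q22.3, with MX1 and MX2, had 5, 15q21.1, with B2M, had 4, and 11p15.5, with the IFITM genes and IRF7, had 4. In 4 of the 19 bands the count was 0, among them 4q21.1, with CXCL9 to CXCL11. A band is far larger than a gene, so these counts do not place a peak at any of the genes named. The share in these bands was 4.23% with lists of equal length and 3.89% at equal fragment number, where regions of all 4 libraries stood at 3.84% and 4.44%.

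**Figure D3:**
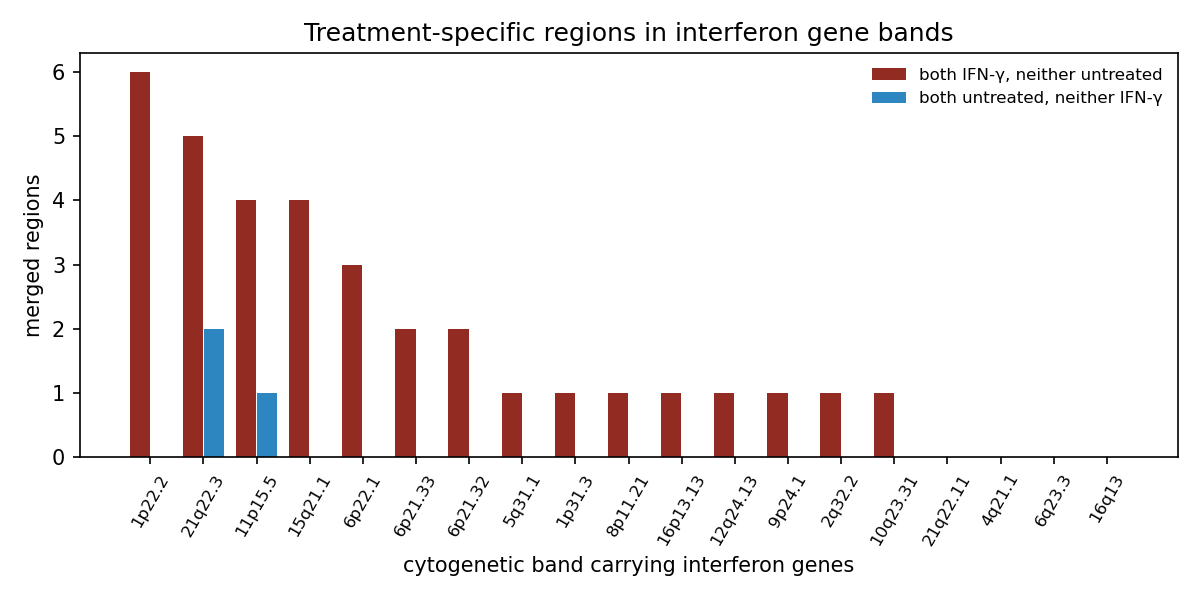
Bars give the number of merged regions (y axis) in each of 19 cytogenetic bands that carry interferon genes (x axis), in red for regions with a peak in both IFN-γ libraries and neither untreated one and in blue for the opposite. The band 1p22.2 has 6 red regions, and blue regions appear in 21q22.3 (2) and 11p15.5 (1).

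Peaks were not spread evenly along chromosome 15. Between 62 and 87 Mb, a stretch chosen for its raised local expectation, lay 992 untreated Bethyl, 271 untreated Novus, 234 IFN-γ Bethyl and 1295 IFN-γ Novus peaks, against 492, 199, 221 and 719 on the rest of the chromosome. Median fold enrichment inside the stretch was 3.64, 4.07, 4.68 and 3.64 in that order, below the medians of 4.76, 4.66, 5.28 and 4.37 outside it. Fold enrichment is a ratio to the local expectation, so the choice of the stretch favours lower values inside it.

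**Figure D4:**
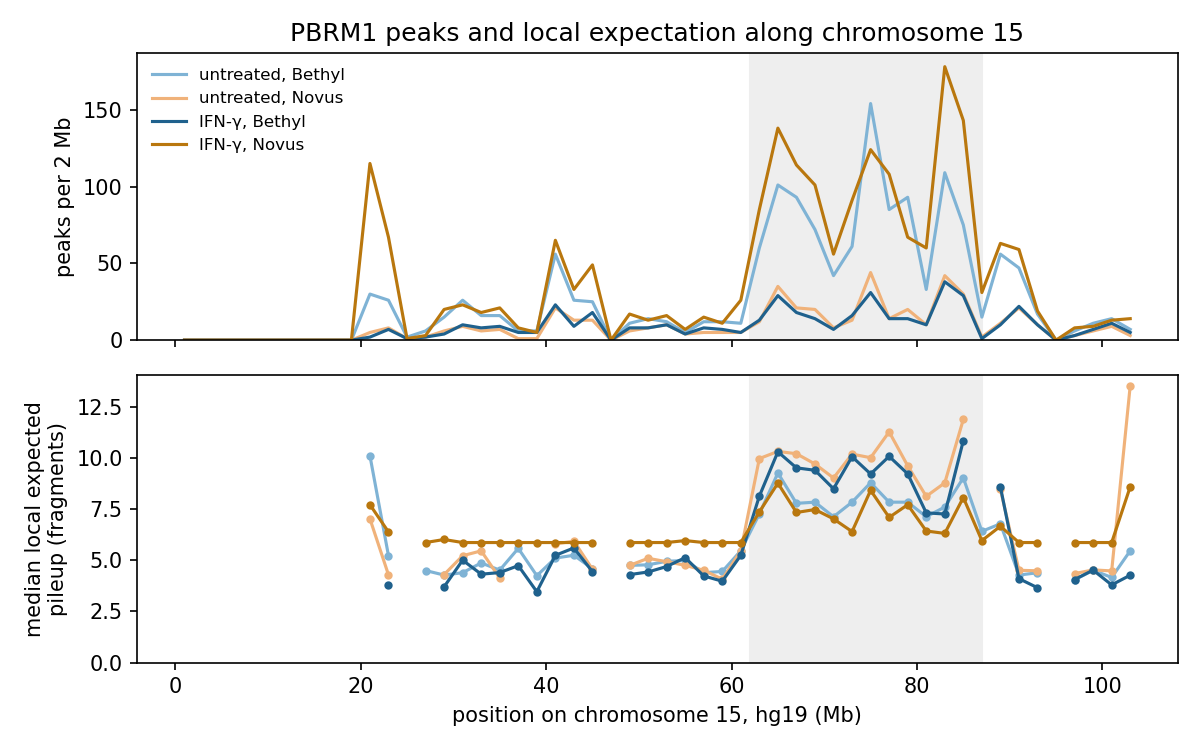
Lines give peaks per 2 Mb (upper panel) and the median local expected pileup in fragments (lower panel) along chromosome 15 in hg19 (x axis, Mb) for the 4 libraries, with the stretch from 62 to 87 Mb shaded. Inside it the expected pileup is 8.03, 9.98, 9.40 and 7.40 in untreated Bethyl, untreated Novus, IFN-γ Bethyl and IFN-γ Novus, against 4.76, 4.88, 4.61 and 5.87 in the rest of the genome.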

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

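Chosen only after the result was seen were the thinning to equal background coverage, both tests of peak strength, and the requirements that a difference exceed the spread between pairs, that it hold in every setting, and that peak strength be compared with shared regions and with untreated Novus peaks. The number of PBRM1 peaks moved in opposite directions with IFN-γ for the antibodies, to 0.477 of the untreated number with Bethyl and to 2.79 times it with Novus, a difference that was not tested with 1 library per group. Against background coverage as the whole cause, the Novus ratio was still 2.82 times the Bethyl ratio after thinning to equal coverage, with a range of 2.77 to 2.83 over 20 further draws. After thinning to equal fragment number it was 1.22 (1.21 to 1.27 over 20 further draws), down from 5.07 without thinning at the same p threshold. This lies between the bounds set before that test, 1.2 for a full account and 1.5 against one, and it left coverage unequal the other way, at 3.01 fragments for IFN-γ Bethyl and 1.58 for IFN-γ Novus, so how much of the opposite movement comes from depth stays open. Exchanged antibody labels in one treatment cannot be told apart from correct ones, because pairs of one antibody overlapped by 1.51 percentage points more than crossed pairs on average, while the pairs of each kind spread wider than that. The bound set before that test against an exchange, over 1 percentage point, was passed, and the requirement on spread came after.

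Regions with peaks in both IFN-γ libraries and neither untreated one could come from weak peaks near the calling threshold. This is open for most of them, since 70.8% ranked at or under the 50th percentile in IFN-γ Bethyl and 32.17% in IFN-γ Novus, against 38.3% and 3.40% of regions in all 4 libraries, and a weak true gain would look alike. For the strongest peaks it stays open too: of 1047 IFN-γ Bethyl peaks of the top 10% on chromosomes 1 to 22 and X, 26 (2.48%, 1.63 to 3.62) were absent from untreated Bethyl, which was deeper, at 1.00 against 0.583 in relative fragment number, and 0 (up to 0.352%) from IFN-γ Novus, the deepest at 2.16. Of such untreated Novus peaks, 2 of 964 (0.207%, up to 0.747%) were absent from untreated Bethyl, but 59 of 1023 (5.77%, 4.42 to 7.38) on all chromosomes. The IFN-γ Bethyl count was 26 in both cases, of 1048 peaks on all chromosomes. Only the untreated Novus reference thus depends on the chromosomes counted. On chromosomes 1 to 22 and X the intervals of these shares were apart, but each share comes from single libraries. A response at interferon loci, the biological explanation tested, cannot be told apart from depth: 6.25% of these regions lay in interferon gene bands, where they numbered 14.3 per 100 regions of all 4 libraries against 8.27 everywhere, a ratio at the 97.8th percentile of 10000 random sets of 19 bands, and the share was above that of regions in all 4 libraries in 7 of 8 settings, with separate intervals in 2 and the order turned at equal fragment number. The condition set before the test asked for separate intervals. With the lists as deposited it was met, at 4.37 to 8.62 against 3.18 to 4.10 for regions of all 4 libraries. The requirement that the difference hold in every setting came after. The bands need not hold every interferon gene, and they leave out 14q32.2, the band of the leading IFN-γ region. The test therefore covers these bands and not interferon loci as a whole.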

How the results depend on the processing

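Thinning to equal coverage or fragment number was chosen after seeing the data, as were all alternatives for the sampled promoters, the CpG islands and the interferon bands. A −log10 q of at least 5 moved none of the 19 results, and counting every summit line changed no list length. A fold enrichment of at least 4 moved 9 results and left 10, and equal lists moved 10 and left 5. No paired analysis was possible because the labels give no replicate numbers, each group has 1 library and the results come from no test across libraries. Treatments were compared within each antibody. Alternatives for motif content, for gene lists and for exon or intron location were not run, as no full hg19 annotation or sequence was used here. The peak number of IFN-γ Novus was 17632 at a fold enrichment of at least 4, 13384 at equal coverage and 5414 at equal fragment number, where untreated Bethyl had 11337 and untreated Novus 4990.

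Overlaps depended on how a shared site was defined and on list length. For untreated Novus in Bethyl, 93.0% became 78.0% with equal lists, 93.6% on chromosomes 1 to 22 and X, 43.3% with 50% reciprocal overlap, 61.2% with summits within 200 bp, 89.9% at equal coverage and 83.2% at equal fragment number. For IFN-γ Bethyl in Novus, 98.1% became 95.5% at a fold enrichment of at least 4, then 78.4% (equal lists), 59.0% (reciprocal), 66.1% (summits), 83.6% (coverage) and 42.7% (fragments). For IFN-γ in untreated Bethyl, 90.9% became 88.3%, 73.3%, 58.9%, 60.1%, 83.6% and 72.0% in the same order. For untreated in IFN-γ Novus, 94.3% became 92.2%, 74.7%, 38.6%, 61.1%, 82.5% and 50.2%, and 94.9% on chromosomes 1 to 22 and X. Thinning removes peaks by construction, and the cause of the other differences was not tested.

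Regions of the IFN-γ combination numbered 1118 with summits within 200 bp, and in every other setting run their count stayed within 1.5 times of 544. Those of the untreated combination went from 183 to 583 with equal lists, 477 with reciprocal overlap, 780 with summits, 373 at equal coverage and 370 at equal fragment number. The IFN-γ combination outnumbered the untreated one in every setting run, by 1.32 to 2.97 times. A site missing from a list was not detected at that library's depth, which does not show that it was unoccupied.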

Other observations

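Chosen after the result was seen in this part were the test of the local expectation on chromosome 15 and the test of peak widths. A stretch of chromosome 15 from 62 to 87 Mb stood out in all 4 lists. It makes up 0.823% of the sequence of chromosomes 1 to 22 and X and held 992 untreated Bethyl peaks (4.52%, 4.25 to 4.80), 271 untreated Novus peaks (2.65%, 2.35 to 2.98), 234 IFN-γ Bethyl peaks (2.23%, 1.96 to 2.53) and 1295 IFN-γ Novus peaks (4.54%, 4.298 to 4.78). It was the longest run of raised local expectation in the genome by the untreated Bethyl list, at 25 bins of 1 Mb where the next had 5. The median expected pileup inside was 1.69, 2.05, 2.04 and 1.26 times that outside, in the order untreated Bethyl, untreated Novus, IFN-γ Bethyl and IFN-γ Novus.

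An extra copy of this stretch in the cell line stays open, although HAP1 is known to carry an additional fragment of chromosome 15. In a near-haploid line it would bring a ratio near 2, as in untreated Novus and IFN-γ Bethyl, while the lowest ratio was 1.26, in IFN-γ Novus, where the expectation outside equalled the background coverage, 5.87, and so could not be lower. The stretch was chosen on one list for its raised expectation, and if one control served every library the 4 ratios are not independent. Weak peaks that pass the threshold because of higher coverage may add to the count, but a filter on fold enrichment cannot decide this. Fold enrichment is a ratio to the local expectation, for which the stretch was chosen. Such a filter therefore removes more peaks inside the stretch by construction. At a fold enrichment of at least 4 the share fell to 1.92% in untreated Bethyl and 2.42% in IFN-γ Novus, so that the full share was at least 1.87 times as high. A share above 0.823% was left in all 4 lists at that threshold, with 1.80% in untreated Novus and 1.79% in IFN-γ Bethyl. No biological explanation beyond copy number was tested.

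Strong IFN-γ peaks were examined as single sites after their values were seen. Of the IFN-γ Bethyl peaks in the top 10% of that list, 25 overlapped an IFN-γ Novus peak and no untreated peak. In 14q32.2 there were 3 of them, from 100794526 to 100804112, 100812137 to 100816217 and 100834392 to 100841678 on chromosome 14, with fold enrichments of 20.6, 8.63 and 10.6. A peak of 8459 bp lay in 5q31.1, the band of the interferon regulatory factor gene IRF1, on chromosome 5 from 131811814 to 131820272, at 11.6. Interferon gene bands held 2 of the 25 (8%, 0.984 to 26.0), against 5.25% of all 1048 peaks of the top 10%. The bands were picked for textbook genes and need not hold every interferon gene. They do not include 14q32.2. Without a full gene annotation, the 25 peaks were not placed against single genes. The share therefore does not show that peaks outside the bands lie away from interferon genes. The hypothesis that the 25 peaks are wider than others of like strength gave a negative result. Their median width was 1067 bp, where random draws of 25 peaks of the top 10% gave 814 to 1254 bp. The draws treat peaks as separate sites, while 3 of the 25 lay close together in 14q32.2. The result holds for the median and not for single peaks, the widest of which was 9587 bp.

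By band, the IFN-γ combination was most frequent in 8q24.3 (10 regions), 17q25.3 (9), 19p13.3 (8) and 9q34.3 (8), which also held 52, 74, 97 and 50 regions of all 4 libraries. In 1q44 and 14q23.1, 7 and 6 IFN-γ regions stood beside 9 and 10 regions of all 4 libraries and 0 of the untreated combination. Everywhere, the IFN-γ combination numbered 8.27 per 100 regions of all 4 libraries. The bands named here were picked for their counts among 817 bands. How high such counts would run without a treatment effect was not tested.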
